A study of Mus musculus with 8 samples.

How the data were processed

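RNA of 8 pooled samples of sorted CD4 T cells was hybridised to 8 Illumina mouse bead arrays, 1 for each combination of tissue (spleen or small intestine), cell type (Treg or Tcon) and genotype (control or K14). Per the labels, each pool held cells of several mice of both sexes aged 7 to 14 weeks, total RNA was cleaned up and biotin-labelled, and a kit for Illumina arrays made the labelled cRNA. The deposited table gives, for each array, a probe intensity on a linear scale and a detection p-value per probe, per the file headers. Neither background correction nor normalization of these intensities is given in the sources used here, and the medians of the 8 arrays differed, from 211.4 to 250.2. The authors also deposited log2 values of the same arrays, with column medians of 8.28 to 8.30. On each array their rank order was the same as that of the intensities (Spearman correlation 1), while their normalization method and any centring stay unknown, so these values served only as an alternative. The replicate numbers in the sample titles run with the genotype and do not mark repeats, and no chip is given in the file.

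Samples were grouped by the labels. In R 4.3.3 with limma 3.58.1, the background was estimated from the detection p-values and removed by normexp (nec), an offset of 16 was added, and arrays were quantile-normalized and taken to log2. Gene names came from the supplied table of the platform's probes and genes: 23978 of 25697 probes had 1 gene symbol, 0 had several and 1719 had none here. A probe was kept with a detection p under 0.05 on at least 2 of the 8 arrays, which left 10021 named probes, where 1373 would pass by chance if no gene were expressed. The probe with the highest mean stood for its gene, giving 7916 genes, and 13714 probes were detected on no array. The number of arrays limits the precision that can be stated.

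Treg against Tcon, K14 against control and gut against spleen were each fitted over all 8 arrays with the 4 matched pairs as blocks, so that the error is the spread of 4 differences. The pairing comes from the labels: both arrays of a pair share the other 2 factors. The genotype difference within Treg and within Tcon, its difference between cell types and between tissues, and the tissue difference between cell types were fitted with a term per group and 2 residual degrees of freedom. limma's moderated test with Benjamini-Hochberg adjustment over all genes was used at an adjusted p of 0.05. Each difference is signed as first group minus second. Since arrays in a comparison came from pooled RNA, p-values measure only the spread between these arrays. Cells of each tissue were a preparation of their own, so preparation and tissue coincide.

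The 24 gene lists were fixed from general T cell biology, and the comparisons, the rule for naming genes and most alternatives were set with them, before the data were examined. Lists were tested with camera (inter-gene correlation 0.01), adjusted over the lists of a comparison, with camera at an estimated correlation and fry as alternatives. Listed genes without a named probe here or below the detection filter were not analysed here. That left 17 of 20 Treg core, 17 of 22 effector Treg, 18 of 28 cell cycle, 15 of 19 interferon, 8 of 8 MHC class II, 11 of 17 myeloid, 5 of 12 B cell, 8 of 19 epithelial and 2 of 7 mast cell and erythroid genes. The genes named in each comparison are the 10 with the largest increases and the 10 with the largest decreases among those past the test with 1 direction in every pair. Where fewer than 10 passed, the 5 highest and 5 lowest with 1 direction in every pair and detected on every array of the brighter side (on all 8 arrays for differences between differences) are named as values. Up to 4 list members with the largest differences, and Foxp3, H2-Ab1, Il2ra, Ctla4, Nr4a1, Cd5 and Mki67 where measured, complete the rule, and within single pairs the 3 highest and 3 lowest genes are named. Predicted and unnamed transcripts were skipped. Within single pairs a list's median was placed among 10000 random lists of the same size matched on mean expression.

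The pipeline was tested on simulated data with 200 changed genes in each of 5 runs over 7916 genes. For Treg against Tcon it found 11.6% of genes changed 2-fold, 69.6% at 4-fold, 90.0% at 8-fold and 94.0% at 16-fold, and for gut against spleen 7.6%, 62.0%, 86.0% and 93.2%. Within Treg the genotype comparison found 0% at 2-fold, 5.2% at 4-fold, 47.6% at 8-fold and 70.8% at 16-fold. The share of false calls was 3.82% to 7.21%. A moved list was found in 5 of 5 runs and an unmoved list in 0 of 5. These runs do not show how correlation between the genes of a list affects its call. On the measured arrays every list call was lost with an estimated correlation. The runs therefore do not vouch for the list calls made at the preset correlation.

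Alternatives were the authors' values, no background correction, median centring, an offset of 50, no detection filter, detection on at least 4 arrays, the mean of a gene's probes, a variance trend with robust fitting, fits without pair blocks, fits with other terms, and each pair left out in turn. Fits without both spleen arrays labelled K14 and their partners, lists with each pair left out, and lists without the genes above 60000 intensity units on any array, were added after seeing the data. Differences with readings raised to the lowest signal above background on their array were also added then. Median centring moved the median of all genes to -0.12 for the genotype difference in Tcon and to 0.12 for the genotype difference between gut and spleen, and under no other setting was a median over 0.1 from 0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.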

Results

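Gene expression was measured with 8 Illumina mouse bead arrays on RNA of CD4 T cells sorted from the spleen or the small intestine, called gut here. Treg, the Foxp3-expressing regulatory T cells, were sorted as live TCRb+CD4+CD8-B220- cells that carried the GFP reporter of Foxp3, and Tcon, the conventional T cells, as the GFP-negative cells of the same gate. Control mice carried 1 working copy of the MHC class II locus, and K14 mice lack MHC class II outside the thymus, per the labels. Each of the 8 combinations of 2 tissues, 2 cell types and 2 genotypes was measured on 1 array with RNA pooled from several mice, so no combination had a replicate. Errors below are limma's moderated standard errors of a difference, from its spread over 4 pairs of arrays. A difference within a cell type is the mean of 2 pairs, and its error pools the spread over Treg and Tcon. The number of arrays limits the precision. Between 8822 and 9677 of 25697 probes were detected per array, and median signals ran from 211.4 to 250.2. The highest signal per array was 70144.7 to 72192.3 units and the next ones lay close to it (rank 20 at 67625.2 to 69866.9), so signals above 60000 units are called near the top of the scale here and taken as lower bounds. Across the genes tested, arrays that differed only in genotype correlated at r = 0.940 to 0.957. Those that differed only in cell type correlated at 0.918 to 0.949, and those that differed only in tissue at 0.901 to 0.937. These correlations are across genes, which are not independent replicates.

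H2-Ab1, the MHC class II beta chain gene that the K14 line lacks outside the thymus, was detected on all 8 arrays. Its brightest probe was higher on the array labelled K14 in 3 pairs and slightly lower in gut Treg. It read, on the log2 scale, 11.63 in spleen Tcon and 11.02 in spleen Treg of control mice, against 13.20 and 13.38 on the arrays labelled K14. In the gut it read 12.25 in Tcon and 10.995 in Treg of control mice, against 12.87 and 10.94 on the arrays labelled K14. The mean difference, K14 minus control, was 1.12 ± 0.43 (SE, 4 pairs, limma adjusted p = 0.602). Of the 4 probes for the gene, 3 were bright, and the dim one read 254.7, 299.1, 367.1 and 273.7 intensity units on the control arrays and 207.2, 202.8, 201.3 and 202.5 on the arrays labelled K14. That dim probe was above background on 1 array, in gut Tcon of control mice, and was singled out after its values were seen. Probe positions relative to the altered part of the gene are not known here, and a probe outside it checks nothing. Because H2-Ab1 does not settle the labels, genotypes below are those of the arrays' labels, and every direction between genotypes rests on them.

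The comparison of Treg with Tcon asks which genes mark the regulatory cells in both tissues and genotypes. Treg arrays had more RNA of Klrg1, an inhibitory receptor of effector lymphocytes, by 5.55 ± 0.55 log2 (SE, 4 pairs, adjusted p = 0.0405). Nrp1, a receptor common on thymus-derived Treg, rose by 3.95 ± 0.36, Ebi3, a subunit of interleukin 35, by 3.79 ± 0.42, and Tnfrsf9, the costimulatory receptor 4-1BB, by 3.63 ± 0.38. Il2ra, the alpha chain of the interleukin 2 receptor, rose by 2.66 ± 0.27 (adjusted p = 0.0409). It lay below background on every Tcon array, so the arrays bound its difference at at least 3.63-fold. On the Tcon side, Il4, a type 2 helper cytokine, was lower in Treg by a log2 difference of -3.82 ± 0.39, the chemokine Xcl1 by -4.05 ± 0.43 and the lectin receptor Klrd1 by -4.15 ± 0.49. All of these genes moved in 1 direction in 4 of 4 pairs.

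By limma, 56 of 7916 genes differed between Treg and Tcon after adjustment, 44 higher and 12 lower in Treg, and all 56 kept 1 direction over the 4 pairs. Besides those named, the genes with the largest increases were Actg2, a smooth muscle actin, at 3.94, Cd83, an activation antigen, at 3.66, Noxa1, an activator of NADPH oxidase, at 3.65, Dgat2, an enzyme of triglyceride synthesis, at 3.64, Gjb2, a gap junction protein, at 3.63, and the tyrosine kinase Src at 3.45. A bound is given where a gene was below background on every array of the dimmer side, and compares the brighter mean with the lowest signal still above background, or with the dim probe itself where that was higher. It was at least 6.25-fold for Noxa1 and at least 5.49-fold for Dgat2. The largest decreases were in Aqp9, a glycerol and water channel, at -5.79 ± 0.36 (adjusted p = 0.0356), and in Pdlim4, an actin-binding adaptor, at -4.94. With each reading below the lowest signal above background raised to it, they were -4.74 and -4.46. St3gal6, a sialyltransferase, followed at -3.73, Tdrp at -3.51, Lrrc75b at -2.66 (at least 2.72-fold), Tgfbr3, a coreceptor of TGF-beta, at -2.54, and Rgcc, a cell cycle regulator, at -2.09. Of the 4 arrays of the dimmer side, 1 detected Aqp9 and Klrd1, 2 detected Pdlim4, Tdrp and Gjb2, and 3 detected Klrg1, Ebi3, Src, Il4, St3gal6 and Tgfbr3, so part of each difference is against background.

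Of the 17 measured genes of the Treg core list, 16 were higher in Treg, 6 passed over all genes and 14 passed adjusted over the list alone. Their mean difference was 2.31 (camera adjusted p = 5.79e-14, and adjusted p = 0.212 with an estimated correlation). The list's median was 2.78 in the spleen control pair, 2.38 in the spleen K14 pair, 2.35 in the gut control pair and 1.74 in the gut K14 pair. Ikzf2, the Treg transcription factor Helios, had a difference of 3.15 ± 0.48 (adjusted p = 0.0830, at least 3.39-fold) and Tnfrsf4, the costimulatory receptor OX40, of 3.09 ± 0.49 (adjusted p = 0.0865). Neither these nor Ctla4, an inhibitory receptor near the top of the scale in gut Treg, at 2.58 ± 0.83 (adjusted p = 0.252), nor Cd5, a negative regulator of TCR signals, at 0.65 ± 0.34 (adjusted p = 0.443), passed. The Foxp3 probe in use read 6.76 to 7.08 on all 8 arrays, close to background, and its difference was -0.16 ± 0.14 (adjusted p = 0.637), so it does not check the sort. The effector Treg list rose as well, with 15 of 17 genes higher, 3 passing over all genes and 11 adjusted over the list alone (mean 1.73, adjusted p = 1.43e-08, and adjusted p = 0.173 with an estimated correlation). Its member Itgae, the integrin chain CD103, stood at 4.51 ± 1.09 (adjusted p = 0.174) and was near the top of the scale in gut Treg of the K14 label.

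**Figure D1:**
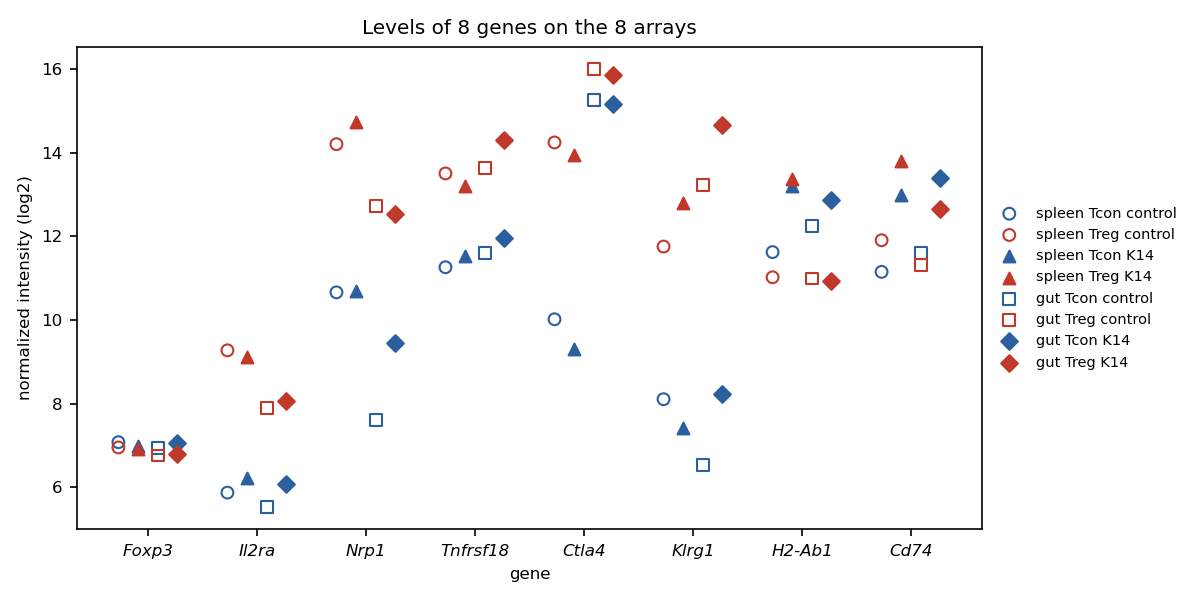
Normalized intensity (log2, vertical axis) of 8 genes (horizontal axis) on each of the 8 arrays, 1 point per array; colour gives the cell type, shape the tissue and genotype, and filled points are arrays labelled K14. Foxp3 lay at 6.76 to 7.08 on all arrays, and Ctla4 reached 15.16 to 16.01 on the 4 gut arrays.

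Lists of conventional and other lymphocytes went the other way. All 10 genes of the resting and central T cell list were lower in Treg (mean -1.20, adjusted p = 1.08e-05, and adjusted p = 0.186 with an estimated correlation). None passed over all genes and 6 did adjusted over the list alone; Igfbp4, a binding protein of insulin-like growth factors, stood at -3.28 ± 0.64 (adjusted p = 0.126) and the survival gene Bcl2 at -1.88 ± 0.32 (adjusted p = 0.100). All 6 genes of the NK and NKT cell list were lower, 1 passing over all genes and 6 adjusted over the list alone (mean -1.73, adjusted p = 1.25e-05, and adjusted p = 0.308 with an estimated correlation). Of the helper lineage and cytokine list, 12 of 14 genes were lower, among them Ifng at -2.86 ± 0.45 (adjusted p = 0.0851) and Tbx21, the type 1 helper regulator, at -2.30 ± 0.28 (adjusted p = 0.0511). That list's mean was -1.23 (adjusted p = 0.00117, and adjusted p = 0.593 with an estimated correlation), with 1 gene passing over all genes, and 1 higher and 3 lower adjusted over the list alone. Its Treg minus Tcon difference was lower in gut than in spleen, by -1.40, so the mean does not hold alike for both tissues.

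Ribosomal protein genes were lower in Treg, 45 of 50 of them, by a mean of -0.34 (adjusted p = 6.42e-07, and adjusted p = 0.446 with an estimated correlation). That count and mean include genes near the top of the scale. Without these, 32 of the 50 remained, with a mean of -0.47 (camera adjusted p = 6.36e-08). Oxidative phosphorylation genes were lower in 50 of 63 cases, by -0.20 (adjusted p = 0.000449, and adjusted p = 0.359 with an estimated correlation). No gene of either list passed, over all genes or adjusted over the list alone. The TCR-induced list was higher in Treg by 0.68 (11 of 13 genes, 1 passing on either count, adjusted p = 0.00475, and adjusted p = 0.446 with an estimated correlation). The cell cycle list had a mean of 0.40 (15 of 18 genes, 0 passing on either count, adjusted p = 0.0109, and adjusted p = 0.857 with an estimated correlation). With a pair left out its mean ranged from 0.14 to 0.63, the lowest without the spleen K14 pair (adjusted p = 0.316). The list's Treg minus Tcon difference was lower in gut than in spleen, by -0.92. Myeloid and dendritic cell markers were lower in Treg in 10 of 11 cases (mean -0.78, 0 passing on either count, adjusted p = 0.00575, and adjusted p = 0.446 with an estimated correlation). Their adjusted p was 0.127 without the gut K14 pair, whose median was -2.34. The other pairs' medians were -0.56 in gut control, 0.04 in spleen K14 and -0.20 in spleen control.

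The 56 calls compare with 1209 genes at an unadjusted p under 0.05, where 395.8 are due by chance. Of all genes, 25.5% kept 1 direction over 4 pairs against a chance share of 12.5%. That share takes the pairs as independent, which is not known here. The gut control pair includes the Tcon array on which 25 of 26 exocrine pancreas genes were detected. With any 1 pair left out, be it gut K14, gut control, spleen K14 or spleen control, 0 genes passed by limma and 918 to 1078 had an unadjusted p under 0.05. With the authors' values 63 of 100 calls were higher in Treg, against 44 of 56 here. Every list call above was lost with an estimated correlation. With fry, which tests whether a list's genes moved 1 way and does not compare them with other genes, the Treg core, effector Treg, resting, NK and ribosomal lists passed.

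The comparison of arrays labelled K14 with controls asks which transcripts depend on MHC class II outside the thymus. No single gene passed by limma, so the highest and lowest differences that follow are values of genes with 1 direction in 4 of 4 pairs. Foxp3, Il2ra, Ctla4 and Cd5 are named by rule whether or not they kept 1 direction. Bub1b, a mitotic checkpoint kinase, was at 2.46 ± 0.25 (SE, 4 pairs, adjusted p = 0.186), Fcer1g, the Fc receptor gamma chain of myeloid and NK cells, at 3.06 ± 0.27 (adjusted p = 0.186), and the hemoglobin gene Hba-a1 at 2.95 ± 0.40 (adjusted p = 0.242). Stard8 was at 3.10 ± 0.60 and Slco2b1, an organic anion transporter, at 2.51 ± 0.53. On the lower side stood the membrane protein Emp1 at -2.90 ± 0.78, Xkr8, a lipid scramblase, at -2.61 ± 0.69, Trim36, a ubiquitin ligase, at -2.58 ± 0.45, the claudin Cldn10 at -2.54 ± 0.77, and Sccpdh at -2.45 ± 0.32, none past the test. Of the 4 arrays of the dimmer side, 1 detected Emp1, 2 detected Fcer1g, Stard8, Slco2b1, Xkr8, Trim36 and Cldn10, and 3 detected Bub1b, Hba-a1 and Sccpdh. Foxp3 differed by 0.01 ± 0.14, with a sign that turned under median centring (-0.0363). Il2ra, detected on 2 of 4 control arrays, differed by 0.22 ± 0.18, Ctla4 by -0.31 ± 0.17 and Cd5 by -0.64 ± 0.33 (adjusted p = 0.682). Nr4a1 was detected on no array, and Mki67 was not analysed here.

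Cell cycle genes rose as a list on the arrays labelled K14. Of 18 genes, 16 were higher and 13 were higher in all 4 pairs, with a mean of 1.06 (adjusted p = 1.71e-12, and adjusted p = 0.358 with an estimated correlation). None passed over all genes and 11 passed adjusted over the list alone. Its median difference was 0.97 in gut Tcon, 1.08 in gut Treg, 0.41 in spleen Tcon and 1.16 in spleen Treg. Nusap1, a spindle protein detected on 3 of 4 control arrays, stood at 2.34 ± 0.51, Kif11, a spindle motor, at 1.96 ± 0.36 (at least 2.13-fold) and the mitotic kinase Cdk1 at 1.89 ± 0.21 (at least 1.87-fold, adjusted p = 0.186). All 15 genes of the interferon response list were higher, by a mean of 0.54 (0 passing on either count, adjusted p = 1.15e-06, and adjusted p = 0.358 with an estimated correlation). Oasl2, an oligoadenylate synthetase relative, was at 1.33 ± 0.39 and the interferon regulator Irf7 at 0.91 ± 0.26.

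Markers of other cell types moved with the same arrays. All 11 myeloid and dendritic cell genes were higher on the arrays labelled K14 (mean 1.30, 0 passing on either count, adjusted p = 7.39e-08, and adjusted p = 0.358 with an estimated correlation). Their medians were 2.68 in spleen Treg, 2.19 in spleen Tcon, 1.39 in gut Tcon and 0.30 in gut Treg. Tyrobp, a signalling adaptor, was at 2.23 ± 0.53 and the lysozyme Lyz2 at 1.92 ± 0.52, each detected on 2 of 4 control arrays. S100a8 and S100a9 of this list were above background on no gut array, so their gut differences are between background readings. All 8 MHC class II presentation genes were higher (mean 0.97, 2 passing adjusted over the list alone and 0 over all genes, adjusted p = 4.21e-05, and adjusted p = 0.367 with an estimated correlation). H2-Eb1 was at 1.78 ± 0.28 and Cd74, the invariant chain, at 1.71 ± 0.17 (adjusted p = 0.186). The list's medians were 1.96 in spleen Treg and 1.62 in spleen Tcon, against 0.58 in gut Tcon and 0.11 in gut Treg. All 5 B cell markers were higher (mean 0.97, 1 passing adjusted over the list alone and 0 over all genes, adjusted p = 0.000440, and adjusted p = 0.361 with an estimated correlation), with medians of 1.48, 1.46, -0.28 and 0.53 in the same order of pairs. Cd79b, a chain of the B cell receptor, stood at 1.35 ± 0.23.

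Smaller lists moved too, each with a call that depended on a pair, and 2 of them also on the detection filter. The immediate early and heat shock list had a mean of 0.43 (adjusted p = 0.00761, and adjusted p = 0.361 with an estimated correlation), with an adjusted p of 0.0935 without the spleen Tcon pair. The NK and NKT list had a mean of 0.90 (adjusted p = 0.0143, and adjusted p = 0.376 with an estimated correlation), and adjusted p values of 0.0838 without the gut Tcon pair, 0.0597 without the spleen Tcon pair and 0.0552 without the detection filter. Its member Fcer1g, also a gene of myeloid cells, stood at 3.06, so that mean is not particular to NK cells. The 2 measured mast cell and erythroid genes had a mean of 1.91 (adjusted p = 0.0134, and adjusted p = 0.361 with an estimated correlation), and adjusted p values of 0.127 without the spleen Treg pair and 0.267 without the detection filter, where the mean was 0.74. Over all genes 0 members of these lists passed, and 1 member of each did adjusted over the list alone. The Treg core list did not pass (mean -0.04, median 0.01, adjusted p = 0.775, 9 of 17 genes higher), nor did the effector Treg list (mean 0.15, adjusted p = 0.314). The same held for the IL-2 and STAT5 target list (mean 0.00, adjusted p = 0.775) and the TCR-induced list (mean -0.07, median 0.12, adjusted p = 0.775). The mean and median of the Treg core and TCR-induced lists thus differed in sign, and the test of the Treg core list went with its mean and that of the TCR-induced list with its median.

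**Figure D2:**
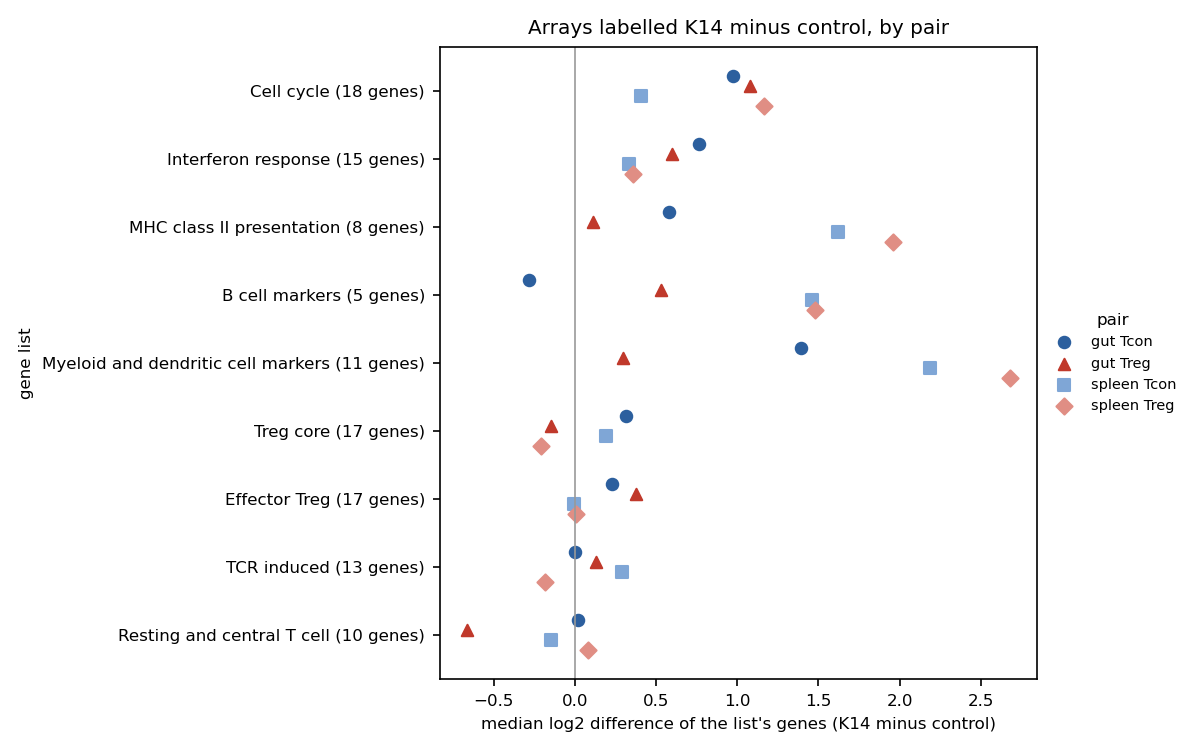
Median log2 difference, arrays labelled K14 minus control (horizontal axis), of the genes of 9 lists (vertical axis), 1 point for each of the 4 pairs of arrays. The cell cycle list lay at 0.41 to 1.16 in the 4 pairs, and the myeloid list at 2.19 and 2.68 in the spleen pairs and 1.39 and 0.30 in the gut pairs.

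By limma 0 of 7916 genes passed between the genotypes, with 634 at an unadjusted p under 0.05 against 395.8 due by chance. Each alternative setting also gave 0 genes, with 309 to 1050 at that level. The 309 came from the fit of 2 groups without pairs. The 1050 came without the detection filter, over 16593 genes, where more are due by chance. With fry 0 of the 8 lists called here passed, with 0.103 the lowest adjusted p. One direction in all 4 pairs was seen for 16.5% of genes against a chance share of 12.5%. The chance share takes the 4 pairs as independent, which is not known here. A difference between the mice of each genotype could recur in several pairs. In data simulated at this spread with 200 changed genes, the same test found 68.8% of genes changed 4-fold and 9.2% of genes changed 2-fold. With fewer changed genes the adjusted threshold is stricter, so these shares do not say what would be found on the measured arrays. The genotype differences of pairs that share no array correlated across genes at r = 0.04 to 0.17, and genes are not independent replicates.

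Within Treg, the comparison of genotypes asks which features of the regulatory cells depend on peripheral MHC class II. All 18 cell cycle genes were higher on the arrays labelled K14, 15 of them in both tissues, by a mean of 1.34 (adjusted p = 4.72e-13, and adjusted p = 0.342 with an estimated correlation). None passed over all genes and 5 did adjusted over the list alone. Nusap1 was at 3.18 ± 0.56 (mean of 2 pairs, SE pooled over Treg and Tcon) and Kif11 at 2.67 ± 0.28 (at least 3.48-fold). Bub1b was at 2.55 ± 0.39 and Top2a, a topoisomerase of dividing cells, at 2.23 ± 0.67. Nusap1 and Bub1b were detected on 1 of 2 control arrays. The Treg core list did not pass, with 11 of 17 genes lower (mean -0.24, adjusted p = 0.195). Of the effector Treg list, Lag3, an inhibitory receptor for MHC class II, stood at -2.32 ± 0.34 (adjusted p = 0.436) and the chemokine receptor Ccr8 at 1.81 ± 0.26 (at least 2.44-fold, adjusted p = 0.436), and neither passed.

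Other genes with 1 direction in both tissues are values only. Mybl2, a cell cycle transcription factor, was at 4.56 ± 0.33 (at least 10.5-fold, adjusted p = 0.435), Lrg1 at 4.51 ± 0.69 (at least 10.8-fold), the collagen gene Col18a1 at 4.48 ± 0.77 (at least 9.60-fold), Prr18 at 4.35 ± 0.30 (at least 16.7-fold) and the DNA repair gene Rad54b at 4.11 ± 1.03. On the lower side stood Denn2b at -4.13 ± 0.68 (at least 6.11-fold), Emp1 at -3.93 ± 1.01 (at least 5.68-fold), the scaffold kinase Cask at -3.84 ± 0.52, Zfp871 at -3.49 ± 0.64 and Rad9b, a DNA damage checkpoint gene, at -3.40 ± 0.86 (at least 4.86-fold). Rad54b, Cask and Zfp871 were detected on 1 of 2 arrays of the dimmer side. H2-Ab1 was at 1.15 ± 0.67 and turned to -0.0559 without the spleen Treg pair, and Il2ra at -0.01 ± 0.24 and 0.156 without it. Ctla4 was at -0.22 ± 0.27 and Cd5 at -0.25 ± 0.44. By limma 0 genes passed, with 499 at an unadjusted p under 0.05, and 0 under each alternative. With fry 0 of the 7 lists called in Treg passed, with 0.106 the lowest adjusted p.

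Other-cell markers were again higher in Treg, and their calls rested on the spleen pair. The myeloid list had a mean of 1.05 (adjusted p = 0.00199, and adjusted p = 0.633 with an estimated correlation), and 0.21 without the spleen Treg pair (adjusted p = 0.381). The MHC class II list went from 0.80 (adjusted p = 0.0123, and adjusted p = 0.633 with an estimated correlation) to -0.0402 without that pair. B cell markers went from 0.84 (adjusted p = 0.0129, and adjusted p = 0.633 with an estimated correlation) to 0.39 without it (adjusted p = 0.381). The 2 mast cell and erythroid genes went from 2.57 (adjusted p = 0.0123, and adjusted p = 0.633 with an estimated correlation) to 1.75 without it (adjusted p = 0.313) and 0.94 without the detection filter (adjusted p = 0.560). The interferon list was higher by 0.47 (12 of 15 genes, adjusted p = 0.00274, and adjusted p = 0.633 with an estimated correlation), with an adjusted p of 0.245 without the gut Treg pair. Oxidative phosphorylation genes were at 0.13 (45 of 63 higher, adjusted p = 0.0288, and adjusted p = 0.633 with an estimated correlation), and at -0.0394 without the gut Treg pair (adjusted p = 0.916). Without the gut Tcon or the spleen Tcon pair their adjusted p was 0.0587.

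In Tcon the same comparison gave higher cell cycle and interferon lists on the arrays labelled K14. Cell cycle genes had a mean of 0.79 (15 of 18 higher, 2 passing adjusted over the list alone and 0 over all genes, adjusted p = 1.77e-05, and adjusted p = 0.434 with an estimated correlation). Bub1b was at 2.37 ± 0.39 (mean of 2 pairs, SE pooled over Treg and Tcon) and Cdk1 at 1.62 ± 0.27 (at least 1.34-fold). All 15 interferon genes were higher (mean 0.62, 0 passing on either count, adjusted p = 6.52e-05, and adjusted p = 0.434 with an estimated correlation), with Irf7 at 1.29 ± 0.31. All 11 myeloid genes were higher in both tissues (mean 1.54, 1 passing adjusted over the list alone, adjusted p = 2.38e-06, and adjusted p = 0.434 with an estimated correlation), with C1qb, a complement chain of macrophages, at 1.87 ± 0.28. Among the 11 genes, S100a8 and S100a9 were above background on no gut array, so their direction in gut is between background readings. Egr2, a TCR-induced transcription factor, stood at -2.16 ± 0.44 (adjusted p = 0.608) and Cd5 at -1.03 ± 0.44 (adjusted p = 0.847), while the TCR-induced list did not pass (mean -0.28 but median 0.16, test with the mean, adjusted p = 0.651).

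The highest values in Tcon were Spon2 at 4.03 ± 0.48 (at least 6.99-fold), the sterol hydroxylase Cyp27a1 at 3.56 ± 0.53 (at least 6.05-fold), the neutrophil chemokine receptor Cxcr1 at 3.47 ± 1.39, the spindle motor Kif15 at 3.46 ± 0.34 (at least 4.79-fold) and Sh3d21 at 3.24 ± 0.79, with Cxcr1 and Sh3d21 detected on 1 of 2 control arrays. The lowest were the autophagy gene Atg9b at -4.49 ± 0.39 (at least 10.96-fold), Ggct at -3.88 ± 0.92, Xkr8 at -3.72 ± 0.76 (at least 8.24-fold), Zc3h13 at -3.45 ± 0.40 (at least 4.54-fold) and Utp23 at -3.38 ± 0.51 (at least 7.74-fold). By limma 0 genes passed, with 492 at an unadjusted p under 0.05, and 0 under each alternative. With fry 0 of the 7 lists called in Tcon passed, with 0.243 the lowest adjusted p. Calls of 4 further lists rested on a pair. MHC class II genes had a mean of 1.13 (adjusted p = 0.000274, and adjusted p = 0.486 with an estimated correlation) and B cell markers of 1.09 (adjusted p = 0.00920, and adjusted p = 0.486 with an estimated correlation). Without the spleen Tcon pair their adjusted p values were 0.213 and 0.648. The immediate early list had a mean of 0.48 (adjusted p = 0.0414, and adjusted p = 0.486 with an estimated correlation), with 0.648 without the spleen Tcon pair. The NK list had a mean of 1.08 (adjusted p = 0.00808, and adjusted p = 0.486 with an estimated correlation), with 0.166 without the gut Tcon pair. On the control array of the gut Tcon pair, 25 of 26 genes for secreted digestive enzymes and other products of the exocrine pancreas were detected, against 3 to 8 on the other arrays.

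Whether the genotype difference itself differs between Treg and Tcon was tested directly. The cell cycle list was higher in Treg than in Tcon by 0.55, all 18 genes in that direction, 0 passing on either count (adjusted p = 0.00705, and adjusted p = 0.849 with an estimated correlation). Its adjusted p was 0.275 without the gut Treg pair, 0.253 without the spleen Tcon pair and 0.824 with fry. Single genes with 1 direction in both tissues included Gtf3c4 at 3.74 ± 0.48, the kinase Vrk1 at 3.35 ± 0.86, the mitotic gene Gtse1 at 3.33 ± 0.49, Cstf3 at 2.88 ± 0.75 and Tctex1d2 at 2.79 ± 0.82. On the other side were the fatty acid receptor Ffar2 at -3.98 ± 2.36, Usp45 at -2.84 ± 0.61, the Toll-like receptor Tlr6 at -2.66 ± 1.61, the tubulin Tubb2b at -2.66 ± 1.26 and P2rx7, a receptor for extracellular ATP, at -2.65 ± 0.65. None passed: limma gave 0 genes, with 386 at an unadjusted p under 0.05 against 395.8 due by chance, and 0 under each alternative. In simulated data this test found 0% of genes changed 16-fold, so single genes could not be called at this size.

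Whether the genotype difference differs between gut and spleen was also tested. The signed difference, K14 minus control, of MHC class II genes was lower in the gut, by -1.40, in 8 of 8 cases (adjusted p = 0.00106, and adjusted p = 0.611 with an estimated correlation), with H2-Ab1 at -1.68 ± 0.47. Myeloid genes lay at -1.06 (7 of 11 lower, adjusted p = 0.00170, and adjusted p = 0.612 with an estimated correlation), and 4 passed adjusted over the list alone. The neutrophil genes S100a8 and S100a9 were above background on 0 of the 4 gut arrays, so no values are compared for them. Both stay among the 11 genes of the list, so its mean, test and counts are partly against background. Epithelial markers lay at -0.97 (8 of 8 lower, 3 adjusted over the list alone, adjusted p = 0.00106, and adjusted p = 0.611 with an estimated correlation), and B cell markers at -0.89 (5 of 5 lower, adjusted p = 0.0153, and adjusted p = 0.611 with an estimated correlation). Oxidative phosphorylation genes lay at 0.23 (46 of 63 higher, adjusted p = 0.0422, and adjusted p = 0.611 with an estimated correlation). Without the gut Treg pair the adjusted p was 0.0577 for MHC class II, 0.285 for myeloid, 0.188 for B cell and 0.530 for oxidative phosphorylation genes. Without the spleen Tcon pair it was 0.163 for B cell and 0.181 for oxidative phosphorylation genes, for which it was 0.102 without the spleen Treg pair. Without the gut Tcon pair it was 0.0985 for epithelial markers. With detection on at least 4 arrays it was 0.117 for B cell and 0.0722 for oxidative phosphorylation genes, and for the latter 0.0685 under median centring. With fry 0 of these 5 lists passed, with 0.233 the lowest. Single genes included Fam124b at 3.27 ± 0.35, Psmc3ip at 3.21 ± 0.34, Ikbip at 2.89 ± 1.21, Spata6 at 2.56 ± 0.85 and Zfp27 at 2.45 ± 0.62. On the lower side were the plasma cell gene Mzb1 at -3.14 ± 0.79, the clock gene Per2 at -3.05 ± 1.49, Smpdl3b at -2.90 ± 0.95, Disp1 at -2.81 ± 0.84 and Fam221a at -2.71 ± 0.75. By limma 0 genes passed, with 493 at an unadjusted p under 0.05, and 0 under each alternative.

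Within single pairs there is no test, and counts are of genes at least 2-fold apart and detected on the brighter array. In gut Tcon 648 genes were higher and 675 lower on the array labelled K14, in gut Treg 516 and 578, in spleen Tcon 481 and 495, and in spleen Treg 611 and 551. Of the 24 extremes, 22 were not above background on the dimmer array, so only their direction and a bound are given. In spleen Treg the histidine decarboxylase Hdc was higher by at least 62.4-fold, Rad54b by 26.9-fold and the formyl peptide receptor Fpr2 by 20.7-fold, and Tspan6 lower by at least 9.45-fold, Zfp871 by 8.94-fold and Zcchc4 by 8.69-fold. In spleen Tcon Cxcr1 was higher by at least 17.005-fold and Sh3d21 by 9.05-fold, Chst3 by 4.65 log2, and Tspan17 lower by at least 13.01-fold, Xkr8 by 17.3-fold and Lyrm7 by 8.40-fold. In gut Treg Col18a1 was higher by at least 13.96-fold, Mybl2 by 16.9-fold and Upp1 by 13.1-fold, and Fam20a lower by at least 58.99-fold, Aldh5a1 by 32.5-fold and Emp1 by 18.2-fold. In gut Tcon Tns4 was higher by at least 36.5-fold and the trefoil peptide Tff1 by 16.2-fold, Lrrc49 by 4.99 log2, and the pancreatic enzyme genes Cela2a lower by at least 368-fold, Pnliprp1 by 32.9-fold and Rnase1 by 21.7-fold. Against random lists matched on expression, the median of the cell cycle list lay at percentile 99.89 or above in all 4 pairs and that of the interferon list at 99.54 or above. A second draw put the cell cycle list in spleen Tcon at 99.84. Random lists drawn gene by gene carry no correlation between their genes, so these percentiles do not show that a list moved beyond chance. The Treg core list lay at percentile 98.3 in gut Tcon, 16.1 in gut Treg, 93.8 in spleen Tcon and 11.8 in spleen Treg.

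The comparison of gut with spleen asks what distinguishes T cells of the intestine. Each tissue's cells were a preparation of their own, so effects of tissue and of preparation cannot be told apart here. Gut arrays had more RNA of Hspa1a, an inducible heat shock protein, by 8.04 ± 0.54 log2 (SE, 4 pairs, adjusted p = 0.0110), and of Il10, an anti-inflammatory cytokine, by 6.43 ± 0.50 (adjusted p = 0.0139). Il10 read 15.97 and 16.10 in gut Treg, near the top of the scale, 13.75 and 14.49 in gut Tcon, and 6.39 to 10.89 in the spleen. Fosb, an immediate early transcription factor, rose by 4.79 ± 0.37, Nfil3, a transcription factor of several lymphoid lineages, by 4.40 ± 0.52, and Bhlhe40, a regulator of cytokine genes, by 4.20 ± 0.20. Genes of other cell types were among the largest differences. Reg3b, an antimicrobial lectin of intestinal epithelium, was higher in gut by 5.43 ± 0.29 (adjusted p = 0.00898, at least 16.7-fold). The neutrophil genes S100a9 and Camp were lower in gut by -5.50 ± 0.60 (at least 19.7-fold) and -4.73 ± 0.70 (at least 13.5-fold), and Slc4a1, the anion exchanger of red blood cells, by -4.53 ± 0.37 (at least 9.62-fold).

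By limma 188 genes differed between gut and spleen, 128 higher and 60 lower in gut, all 188 in 1 direction over the 4 pairs. The rest of the 10 largest increases were Esm1, an endothelial proteoglycan, at 5.52 (at least 20.2-fold), the secreted Wnt modulator Dkk3 at 4.77, the kinase Dapk2 at 4.73, the Notch target Hey1 at 4.68 and Gja1, a gap junction protein, at 4.68 (at least 13.05-fold). The rest of the 10 largest decreases were Il4i1, an amino acid oxidase, at -3.64, the lymphocyte antigen Ly6c1 at -3.41, Tmem108 at -3.05 (at least 4.70-fold), Cnn3 at -2.91, Tdrp at -2.81, the adenylate cyclase Adcy6 at -2.79 and Pld4, a nuclease of B and dendritic cells, at -2.77. Of the 4 arrays of the dimmer side, 1 detected Hspa1a, Fosb, Dkk3 and Pld4, 2 detected Hey1, Il4i1 and Tdrp, and 3 detected Il10, Dapk2, Nfil3, Cnn3 and Adcy6. With readings raised to the lowest signal above background, Hspa1a was at 7.29, Fosb at 4.27, Dkk3 at 3.70 and Pld4 at -2.08.

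Immediate early, effector, TCR-induced and residency lists rose in gut, where tissue and preparation coincide. All 11 immediate early and heat shock genes were higher, 8 passing over all genes and 9 adjusted over the list alone (mean 3.02, adjusted p = 1.30e-11, and adjusted p = 0.148 with an estimated correlation). Atf3 was at 3.88 ± 0.26 (at least 5.63-fold) and Fos at 3.76 ± 0.22. All 17 effector Treg genes were higher, 5 passing over all genes and 10 adjusted over the list alone (mean 1.86, adjusted p = 2.05e-08, and adjusted p = 0.148 with an estimated correlation), Lag3 among them at 2.97 ± 0.37. Of 13 TCR-induced genes 12 were higher, 3 passing over all genes and 5 adjusted over the list alone (mean 1.33, adjusted p = 5.21e-06, and adjusted p = 0.349 with an estimated correlation), with Nfkbid at 2.13 ± 0.16. Cd69, an activation and retention antigen, was near the top of the scale on all 4 gut arrays and at least 3.31-fold higher there. Of 13 gut homing and tissue residency genes 12 were higher, 2 passing over all genes and 9 adjusted over the list alone (mean 1.67, adjusted p = 4.38e-06, and adjusted p = 0.198 with an estimated correlation). Rora, a nuclear receptor, rose by 2.02 ± 0.25 (at least 2.61-fold), and Itgae, near the top of the scale on 1 gut array, stood at 4.02 ± 1.06 (adjusted p = 0.111).

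Cytokine genes rose too. Of 14 helper lineage and cytokine genes 13 were higher in gut, 3 passing over all genes and 7 adjusted over the list alone (mean 1.61, adjusted p = 1.21e-05, and adjusted p = 0.349 with an estimated correlation), with Ifng at 3.83 ± 0.42, the chemokine Ccl4 at 3.66 ± 0.37 and Il4, detected on 3 of 4 spleen arrays, at 3.23 ± 0.36. All 7 follicular helper genes were higher, 1 passing over all genes and 2 adjusted over the list alone (mean 0.99, adjusted p = 0.00809, and adjusted p = 0.376 with an estimated correlation), with the costimulator Icos at 2.06 ± 0.20, and the adjusted p was 0.0646 without the Tcon control pair. The Treg core list had a mean of 0.68 (11 of 17 higher, 0 over all genes, 5 higher and 1 lower adjusted over the list alone, adjusted p = 0.0201, and adjusted p = 0.376 with an estimated correlation), with 0.0884 without the Tcon K14 pair. Nrp1 of that list stood at -1.99 ± 0.34 (adjusted p = 0.0580) and Ctla4, near the top of the scale in gut Treg, at 3.69 ± 0.84 (adjusted p = 0.0858). Without Ctla4 and the other genes near the top of the scale the list had a mean of 0.49 (adjusted p = 0.0442). Glycolysis genes had a mean of 0.39 (adjusted p = 0.0482, and adjusted p = 0.349 with an estimated correlation), with 0.170 without the Tcon K14 pair, 0.0550 without the Tcon control pair and 0.0634 without the Treg K14 pair. The glycolysis list did not pass under median centring (0.132), with the mean of probes (0.0658) or with fry either.

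**Figure D3:**
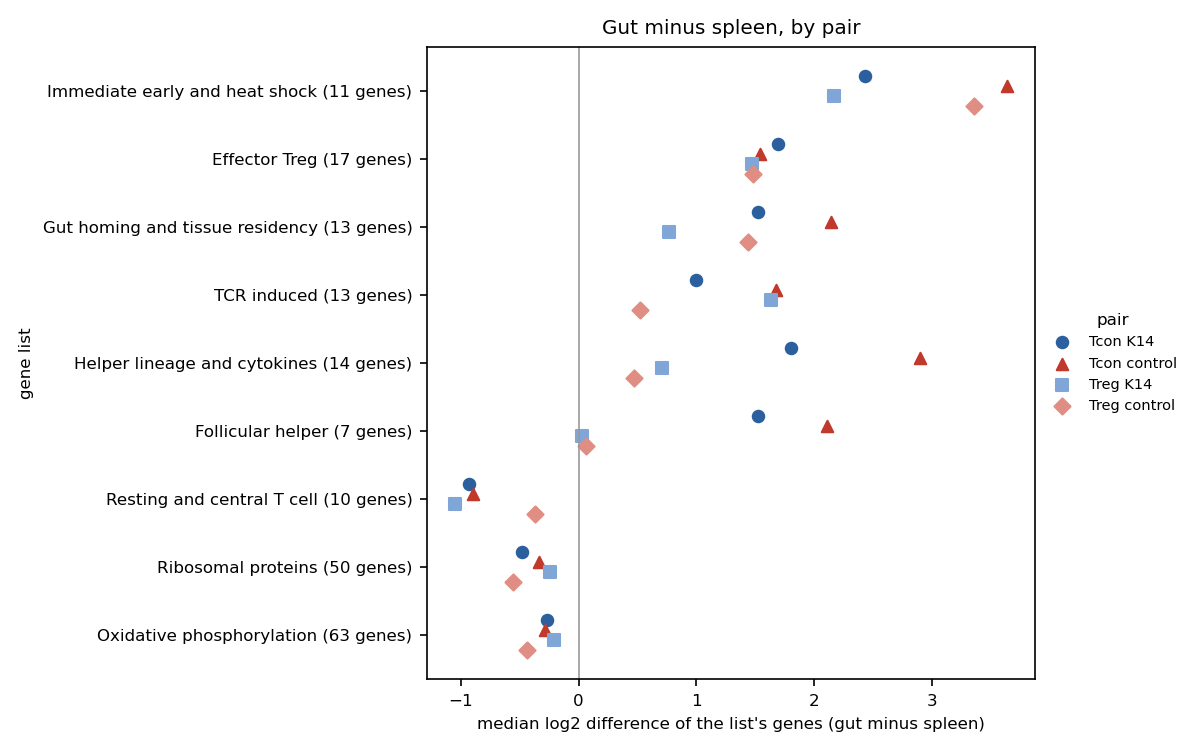
Median log2 difference, gut minus spleen (horizontal axis), of the genes of 9 lists (vertical axis), 1 point for each of the 4 pairs of arrays. The immediate early and heat shock list lay at 2.17 to 3.64, and the follicular helper list at 1.53 and 2.11 in Tcon and at 0.02 and 0.06 in Treg.

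Other lists fell in gut. Ribosomal protein genes were lower in 46 of 50 cases, 3 passing over all genes and 15 adjusted over the list alone (mean -0.44, adjusted p = 8.79e-07, and adjusted p = 0.349 with an estimated correlation). These counts and the mean include genes near the top of the scale. Without them, 32 of the 50 remained, with a mean of -0.60 (camera adjusted p = 2.01e-08). Oxidative phosphorylation genes were lower in 52 of 63 cases, 1 passing over all genes and 0 adjusted over the list alone (mean -0.25, adjusted p = 0.000756, and adjusted p = 0.349 with an estimated correlation). Of 10 resting and central T cell genes 9 were lower, 1 passing over all genes and 4 adjusted over the list alone (mean -0.93, adjusted p = 0.00656, and adjusted p = 0.349 with an estimated correlation), with Id3, a transcriptional inhibitor, at -2.10 ± 0.31. B cell markers were lower in 5 of 5 cases (mean -0.91, 2 adjusted over the list alone and 0 over all genes, adjusted p = 0.0332, and adjusted p = 0.349 with an estimated correlation), with 0.131 without the Treg K14 pair, 0.0702 with the authors' values and 0.196 with detection on at least 4 arrays. Intestinal epithelial markers were higher in 7 of 8 cases, 2 passing over all genes and 4 adjusted over the list alone (mean 1.72, adjusted p = 0.000166, and adjusted p = 0.349 with an estimated correlation). Under the other settings the list's mean ranged from 0.90 to 2.65. The keratin Krt8 rose by 3.33 ± 0.48, and the list's medians were 2.28 and 1.37 in the Tcon and Treg control pairs against 0.62 and 0.43 in the K14 pairs.

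The 188 calls stand beside 1906 genes at an unadjusted p under 0.05 and 34.3% of genes with 1 direction in 4 pairs. Left-out pairs changed the count to 0 without the Tcon K14, the Tcon control or the Treg control pair and to 33 without the Treg K14 pair. The Tcon control pair includes the gut array on which 25 of 26 exocrine pancreas genes were detected. Without both spleen arrays labelled K14 and their gut partners, where myeloid and B cell markers were high, 0 genes passed by limma, with 1237 at an unadjusted p under 0.05. The authors' values gave 242 of 468 calls higher in gut and uncorrected signals 227 of 406, against 128 of 188 here. With fry, 7 lists passed: immediate early, effector Treg, ribosomal, gut homing, TCR-induced, epithelial and resting.

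Whether gut and spleen differ to another extent in Treg than in Tcon was tested last. The signed difference, gut minus spleen, was lower in Treg for the helper lineage and cytokine list (mean -1.40, 12 of 14 lower, 5 adjusted over the list alone, adjusted p = 4.66e-07, and adjusted p = 0.378 with an estimated correlation). The interleukin genes Il17f and Il17a read 8.46 to 9.77 in gut Tcon and were not above background elsewhere, so no difference is given for them. Both stay among the 14 genes of the list, so its mean, test and counts are partly against background. Cell cycle genes were at -0.92, with gut minus spleen means of -0.66 and -0.47 in Treg and 0.14 and 0.57 in Tcon (18 of 18 lower, 0 passing, adjusted p = 9.74e-06, and adjusted p = 0.378 with an estimated correlation). Follicular helper genes were at -1.52 (7 of 7, 3 adjusted over the list alone, adjusted p = 8.98e-05, and adjusted p = 0.403 with an estimated correlation), and IL-2 and STAT5 targets at -0.79 (11 of 12, 1 adjusted over the list alone, adjusted p = 0.000156, and adjusted p = 0.378 with an estimated correlation). The Treg core list was at -0.86 (13 of 17 lower, 2 higher and 4 lower adjusted over the list alone, adjusted p = 0.000756, and adjusted p = 0.429 with an estimated correlation). Ctla4 of that list read 10.02 and 9.31 in spleen Tcon, 14.25 and 13.96 in spleen Treg and 15.16 to 16.01 in the gut, near the top of the scale in gut Treg, so its tissue differences are not compared. Without it and other genes near the top of the scale the Treg core list had a mean of -0.68 (adjusted p = 0.00760). The gut homing list was at -1.30 (9 of 13 lower, 2 adjusted over the list alone, adjusted p = 0.00411, and adjusted p = 0.403 with an estimated correlation), and its call was lost without its 4 members near the top of the scale on some array, Itgae among them (mean -1.06, adjusted p = 0.0868).

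Myeloid markers were at -0.97 in the same test (adjusted p = 0.00790, and adjusted p = 0.429 with an estimated correlation) and MHC class II genes at -0.99 (adjusted p = 0.0221, and adjusted p = 0.689 with an estimated correlation). Without the Treg K14 pair their adjusted p values were 0.548 and 0.594, and without the Tcon control pair 0.0769 and 0.505. Further single genes were the decoy receptor Il1r2 at -3.58 ± 0.41, the prion protein gene Prnp at -3.58 ± 0.38 and the potassium channel Kcnk5 at -3.72 ± 1.24. The higher ones were Bcorl1 at 3.52 ± 0.69, Get1 at 2.90 ± 1.44, Styx at 2.84 ± 0.59, Cdr2 at 2.76 ± 0.75 and Tex2 at 2.71 ± 1.36. None passed: limma gave 0 genes, with 555 at an unadjusted p under 0.05 against 395.8 due by chance, and 0 under each alternative. With fry, the gut homing and the IL-2 and STAT5 lists passed.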

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

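Tests of normalization, of pooled myeloid and B cell lists and of Xist were chosen only after the results they concern were seen. The same holds for tests of lists without genes near the top of the intensity scale. Other tests named here were set before their own values were seen. Of these, the second marker lists and the erythroid markers followed up patterns already seen. Tests of a difference between differences picked out 14 lists. The signed genotype difference, K14 minus control, was higher in Treg than in Tcon for the cell cycle list by 0.55. It was lower in gut than in spleen for MHC class II genes (-1.40), B cell markers (-0.89), myeloid markers (-1.06) and epithelial markers (-0.97), and higher for oxidative phosphorylation genes (0.23). Epithelial means were -1.07 and -0.39 in gut against 0.19 and 0.29 in spleen. The signed difference, gut minus spleen, was lower in Treg than in Tcon for the Treg core (-0.86), cell cycle (-0.92), gut homing (-1.30), helper lineage (-1.40), follicular helper (-1.52), IL-2 and STAT5 (-0.79), MHC class II (-0.99) and myeloid (-0.97) lists. Lower does not mean smaller in size here: in Treg the means were below 0 for cell cycle genes (-0.66 and -0.47), IL-2 and STAT5 targets (-0.18 and -0.23) and myeloid markers (-0.30 and -1.98), and for MHC class II genes in the K14 pair (-1.28). All 14 were mean log2 differences past camera at its preset correlation, and none passed with an estimated correlation. The gut homing call was also lost without genes near the top of the intensity scale (adjusted p = 0.0868).

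Myeloid and B cell markers were higher on the spleen arrays labelled K14, although the gate for TCRb and against B220 would remove both kinds of cell. Second lists of such markers, written before they were tested, were higher too. The lower of the spleen medians was 0.79 for 19 myeloid genes and 0.95 for 13 B cell genes. These lay at percentiles 100 and 99.96 of random lists, which carry no correlation between the genes of a list. So RNA of such cells could account for these markers, and Cd74 and S100a9 reached 13.80 and 12.69 there. Gut medians of the second lists were 0.15 and -0.02 (myeloid) and -0.28 and 0.13 (B cell). Transcription of such genes by T cells of K14 mice, the biological alternative, was not tested.

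The cell cycle list had a higher median on the array labelled K14 in each pair, with 14 to 17 of its 18 genes higher. Dividing myeloid or B cells as their source cannot be told apart from dividing T cells. The pooled fixed lists had a lower median of 1.59 in the spleen, which restates markers already seen there and decides nothing, so this verdict was set to open afterwards. In the gut their median was 0.32 in Treg against 1.20 in Tcon. Erythroid precursors stay open as well: 4 markers had a mean of 0.38, which met the bound set beforehand, but pair medians of 0.11, 0.16, 1.47 and -0.21 did not go one way and the markers lay near the floor, so this verdict was changed to open after the values were seen. Normalization as the whole cause is argued against, since the lowest mean under the other scalings was 0.60 and the list kept its call at the preset correlation, a call that was lost with an estimated correlation (adjusted p = 0.358) and with fry (0.103). More division of T cells in K14 mice was not tested.

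The K14 arrays also differed in genes outside the lists. Eif2s3y, a Y chromosome gene, was detected on the 4 arrays labelled K14 and on no control array, with a mean at least 2.14-fold higher. Xist, which female cells express, was lower in 3 pairs (-0.66, -0.98 and -0.69) and 0.03 higher in spleen Treg. Uty, another Y chromosome gene, was detected on all 8 arrays and was lower on the K14 array in all 4 pairs (-0.44, -0.02, -0.20 and -0.05), and Kdm5d, also on the Y, was detected on no array, so a larger male share of the pools could not be settled. Of the 60 genes around H2-Ab1, 25% kept 1 sign over the 4 genotype pairs, which equals the 95th percentile of windows along the genome, so DNA of another strain there is open too. The verdicts on Xist and on these neighbours were set to open after their values were seen.

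Other splits of the 8 arrays, in a fit of 2 groups without pairs, asked whether chance can be excluded. For gut against spleen only the real split, 1 of 35, reached 267 genes, against 27 for the highest other, the cell type split. A share of 1 of 35 is the smallest these splits can give. It argues against a random grouping of the arrays as the source of the 267 genes. It does not reach the 188 calls of the paired fit. For Treg against Tcon 2 of 35 splits gave as many as the real 27 genes, and the highest other, 267, was the tissue split, a structure of the samples, so this count does not exclude chance. The 33 splits that follow neither tissue nor cell type gave 0 to 2 genes. For K14 against control the real split gave 0 genes, so every split, 35 of 35, gave as many, with 267 the highest other, and this outcome decides nothing. Swaps within pairs, 8 for each comparison, are too few for a share under 0.05: 1 swap reached the real 56 genes for Treg against Tcon (highest other 1), 1 the real 188 for gut against spleen (highest other 0) and 8 the real 0 for K14 (highest other 0), which decides nothing either.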

How the results depend on the processing

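The fits without the spleen arrays labelled K14 and the lists with a pair left out or without genes near the top of the intensity scale were chosen only after the results were seen. Treg against Tcon gave 56 genes, and 100 with the authors' values, 100 without background correction, 113 with a variance trend and robust fitting, 110 in an additive fit, 27 with 2 groups and no pairs, and 2 without the detection filter. Gut against spleen gave 188, and 468, 406, 457 and 462 under the first 4 of these, 288 with an offset of 50, 125 without the detection filter, 322 with detection on at least 4 arrays and 0 without the spleen arrays labelled K14. The cause was not tested, except that left-out arrays leave fewer samples. With a pair left out the counts were 0 to 0 for Treg against Tcon and 0 to 33 for gut against spleen. The other 6 comparisons gave 0 genes under every setting. Each lone array left by a dropped pair is assumed to vary like the others.

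Genes at least 2-fold apart in single pairs changed at 3-fold, with the authors' values and without background correction to 653, 499 and 702 in gut Tcon (1323 before), 444, 368 and 507 in gut Treg (1094), 470, 284 and 403 in spleen Tcon (976), and 547, 425 and 597 in spleen Treg (1162). A chip block was not run, since no chip is given in the file.

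Signs turned for 14 values of genes that had not passed. Foxp3, near background, turned under median centring to -0.0363 for K14 against control, -0.0369 in Tcon and 0.00120 for the genotype difference in Treg minus that in Tcon, and H2-Ab1 for the latter to -0.201 with the mean of probes. With a pair left out, Foxp3 ranged from -0.0276 to 0.0423 for K14 against control, -0.0285 to 0.0252 in Treg, -0.0795 to 0.130 in Tcon and -0.132 to 0.0778 for the genotype difference in Treg minus that in Tcon. H2-Ab1 ranged from -0.0559 to 2.36 in Treg and -1.15 to 1.27 for that same difference of differences (-0.417 without the gut Tcon pair), Il2ra in Treg from -0.171 to 0.156, Ctla4 for the genotype difference in Treg minus that in Tcon from -0.119 to 0.492, and Cd5 for the genotype difference in gut minus that in spleen from -0.102 to 1.52. The lists of MHC class II (-0.0402 to 1.64) and oxidative phosphorylation (-0.0394 to 0.298) in Treg also turned.

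Of the tests of lists past the preset threshold, 475 under other settings kept the call and 115 lost it, among them every one with an estimated correlation. With a pair left out 198 kept it, 36 lost it and 2 turned. Of genes past the threshold, 354 values kept their call under other settings and 56 lost it, against 6 and 178 with a pair left out. Their sizes moved as well. Over the other settings Gjb2 ranged from 1.91 to 3.63, Src from 1.59 to 3.45 and Tgfbr3 from -2.55 to -1.24 for Treg against Tcon. Hey1 ranged from 2.83 to 4.72 for gut against spleen. Nrp1, at 3.55 to 3.97 for Treg against Tcon, moved less.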

Other observations

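The observations here were all chosen after single-pair values were seen, and the list of pancreatic genes was written after 3 of its genes had been seen. The array of gut Tcon from control mice carried transcripts of the exocrine pancreas. Cela2a, a pancreatic elastase, read 15.21 there, 9.73 in gut Treg of control mice and 5.44 to 6.09 elsewhere. The proteases Cela1 and Cpb1 read 12.98 and 12.38 (Cela1 was detected on all 8 arrays, at 7.35 to 10.78 on the others), the lipase relative Pnliprp1 11.73, the colipase Clps 11.35 and Reg1 12.14. Of 26 pancreatic genes with a probe, 25 were detected on that array, with a median of 10.41, and 3 to 8 on each other array, with medians of 5.61 to 5.85.

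Of these genes, 4 are also known from intestine: Zg16, Dmbt1, Spink1 and Reg1. Zg16 read 9.42 on the gut Tcon array labelled K14, and Spink1 9.51 on the gut Treg array labelled K14. The sort for TCRb and CD4 would remove pancreatic cells, and no test here tells cells from free RNA. Every genotype difference in gut Tcon, and every tissue or cell type difference in controls that uses this array, includes these transcripts.

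A Foxp3 probe other than the one in use was detected on 1 array, gut Treg labelled K14, at 427.6 intensity units with a detection p-value of 0.00125.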
